A study of Caenorhabditis elegans with 4 samples.

How the data were processed

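The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) with a polyclonal antibody raised in rabbits against AMA-1, the large subunit of RNA polymerase II of the nematode Caenorhabditis elegans. Per the labels' protocols, mixed-stage embryos of the wild-type strain N2 were harvested after growth under an RNAi protocol, and the series lists a temperature of 20 degrees Celsius. The extract was sonicated, 2 mg of extract with 1% sarkosyl entered each immunoprecipitation, and 10% was taken as input. The libraries were 2 AMA-1 ChIP libraries (replicates 1 and 2) and 2 input DNA libraries. The sample titles carry the tag RiIMB1, which the labels do not spell out. All libraries carry it, so no comparison with another RNAi condition was possible within the series. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

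The deposited data analysed here were 3 peak lists in coordinates of WormBase WS220, per the file headers. Per the submitters' processing notes, the reads were handled with BWA and the ce10 assembly. Each ChIP replicate has its own list, whose source column names MACS without a version. A series-wide list names MACS version 2 per its source column. The calling settings, the use of the input libraries and the way the replicates entered the series-wide list are not given in the sources used here. Start, end and score of each peak were used as deposited, with coordinates counted from 1. The deposited score has no unit in the files. In both replicate lists the lowest score was 50.07, just above 10 times the −log10 of 1e-05 (50), and in the series-wide list it was 1.3, the −log10 of 0.05 at the printed precision. Scores were therefore compared only within a list, to rank or filter peaks and to set medians of classes of peaks of the same list side by side, and the size of such a difference has no physical unit. In the replicate lists 278 and 189 peaks carried a score of exactly 3100 and 8 and 6 peaks a score above it. Values at or above 3100 were treated as tied, because such a ceiling does not rank the peaks that reach it. Read counts, coverage and library sizes were not used here, so the depth behind each peak is unknown. The intervals given for shares of peaks are 95% Wilson intervals, cover counting error only and treat peaks as independent, which neighbouring peaks are not.

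A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The share was compared with 1000 circular shifts of the other list within each chromosome, in a one-sided permutation test whose smallest possible p is 0.001. Scores of shared and other series-wide peaks were compared by a two-sided permutation test of the difference of medians with 100000 resamples. Agreement of scores was given as Spearman's rho across pairs of peaks that overlapped one to one, with a bootstrap interval from 1000 draws, and peaks are not independent replicates. For chromosomes and their parts the shared set was the replicate 1 peaks that overlapped replicate 2. Peak densities used the span from position 1 to the last peak end in any list as the length of each chromosome. The X chromosome was set against the 5 autosomes by an exact permutation over the 6 chromosomes, which cannot give a p below 0.167. The outer and middle parts of chromosomes, from a division into 3 equal lengths, were compared by an exact sign-flip permutation over the 6 chromosomes, whose smallest p is 0.0312. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

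The overlap procedure was tested on simulated lists of 2800 drawn peaks with the widths of replicate 1. In 10 simulated pairs with a planted share of 66.7% on average, the share recovered above the shifts was 63.9% on average, within 3.63 percentage points in each pair, and p was under 0.05 in 10 of 10. In 10 pairs with no planted share it was under 0.05 in 0 of 10. The recovered share is the excess over the shifted mean, as a part of the peaks not matched in shifts. It is not the raw share or the fold given in the results. Simulated peaks were placed evenly at random within chromosomes, planted copies kept their width and nearly their position, and fewer shifts were drawn. Real peaks cluster by region and differ in width between lists, which the simulation did not test.

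The design, the main overlap and score tests and most alternatives were fixed before the data were examined. The exact permutation of X against the autosomes and the Fisher tests of regions at the score ceiling were not part of that plan. The rule for named items was the 20 genes of best mean rank of score over both replicate lists, or, without a usable annotation, the 20 regions of best mean rank. The gene table at hand describes the WBcel235 assembly, whereas the peaks are in WS220 coordinates. The 2 were not joined, so regions are named by position, and the 19 gene lists, the gene biotypes and the gene features planned for testing were not analysed here. Many regions tied at the score ceiling and were ordered by the highest series-wide score inside the region, a choice made after the ties were seen. The alternatives were a reciprocal overlap of 50%, a peak midpoint inside the other peak, the better-scoring 50% of each list, each replicate list alone, the series-wide list and, added after the data were seen, the shared peaks as listed in replicate 2, shifts of 50 to 200 kb, single chromosomes, shifted shares for each 25% of scores, the best-scoring 10% of the series-wide list and the division of chromosomes into outer and middle parts.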

Results

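AMA-1 occupancy was profiled in C. elegans mixed embryos of strain N2, with 2 ChIP libraries and 2 input libraries. The labels give a wild-type genotype, but the growth protocol is named for RNAi and every title carries the tag RiIMB1, so the values are not to be read as those of untreated wild type. The labels do not name the RNAi target. Peaks were listed for each ChIP replicate and once for the whole series. The replicate 1 list held 2838 peaks that covered 13.6 Mb, or 13.6% of the chromosome spans, and the replicate 2 list held 2843 peaks that covered 11.9 Mb, or 11.9%. The series-wide list held 15152 peaks that covered 11.9 Mb, or 11.8%. Replicate peaks were broad, with a median width of 3110 bp (quartiles 1835 and 5958.5 bp) in replicate 1 and 2751 bp (quartiles 1732 and 5243 bp) in replicate 2. Series-wide peaks were narrow, with a median of 345 bp (quartiles 213 and 684.25 bp). The widest peak of replicate 1 spanned 37736 bp and that of replicate 2 spanned 32284 bp. All 3 lists held peaks on chromosomes I, II, III, IV, V and X.

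A first comparison asked how far the replicates marked the same regions. Of the replicate 1 peaks, 2037 (71.8%, interval 70.1 to 73.4%) overlapped a replicate 2 peak, and of the replicate 2 peaks, 2188 (77.0%, interval 75.4 to 78.5%) overlapped a replicate 1 peak. Shifted lists gave 22.9% ± 0.93 (SD over 1000 shifts) and 23.4% ± 0.988, so the observed shares were 3.13-fold and 3.29-fold above chance (permutation test, one-sided, p = 0.001 in each direction, the smallest value 1000 shifts can give). The peaks shared 9.48 Mb, which was 69.8% of the bases of replicate 1 and 79.6% of those of replicate 2, with a Jaccard index of 0.592. By chromosome the share lay between 69.8% on V and 73.3% on X for replicate 1, and between 71.0% on X and 78.8% on V for replicate 2. The chance share differed more, and for replicate 1 it was 30.3% on I and 13.4% on X, so that the observed share was 2.35-fold above it on I and 5.45-fold on X. When an overlap of 50% of each peak was required, 1595 pairs remained, which were 56.2% of replicate 1 and 56.1% of replicate 2 peaks, against 4.36% and 4.38% in shifted lists.

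Nearly all AMA-1 peaks of high score were found in both libraries, and those of low score often in 1. In the lowest 25% of replicate 1 scores, 42.8% of 710 peaks (interval 39.2 to 46.5%) had a replicate 2 partner, against 96.6% of 710 peaks (interval 95.02 to 97.7%) in the highest 25%. For replicate 2 the shares were 53.7% of 711 peaks (interval 50.1 to 57.4%) and 97.05% of 711 peaks (interval 95.5 to 98.1%). Shifted lists gave 17.8% and 30.1% for these lowest and highest parts of replicate 1, and 19.3% and 29.6% for those of replicate 2. Peaks of high score were also wider, with a median of 7680 bp in the highest and 1484 bp in the lowest 25% of replicate 1. Across 1537 pairs that overlapped one to one, scores had a Spearman's rho of 0.75 (bootstrap interval 0.72 to 0.77) and widths one of 0.81. These correlations are across peaks, which are not independent replicates.

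**Figure D1:**
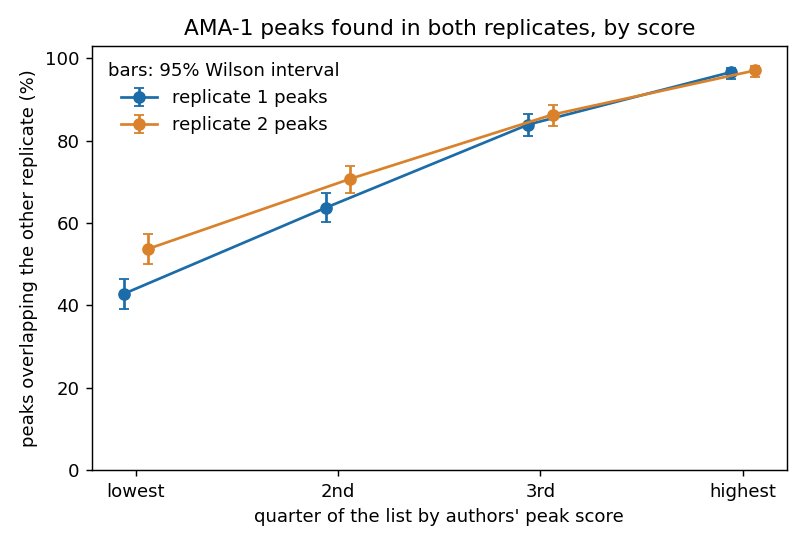
Share of AMA-1 peaks (y axis, percent) that overlap a peak of the other replicate, in 4 equal parts of the list ranked on the authors' score (x axis), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. The share climbs from 42.8% to 96.6% for replicate 1 and from 53.7% to 97.05% for replicate 2.

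Regions at the score ceiling lay on every chromosome. Joining each peak to its best-ranked partner gave 1900 shared regions, and 168 of them (8.84%) reached the score ceiling in both replicates. Of these 168 regions, 34 lay on chromosome IV, 33 on V, 30 on I, 29 on II, 23 on X and 19 on III. X held 13.7% of the regions at the ceiling (interval 9.3 to 19.7%) and 203 of all 1900 regions (10.7%). The share on X of regions at the ceiling did not differ detectably from that of the other shared regions (Fisher's exact test, two-sided, odds ratio 1.37, p = 0.191). Regions at the ceiling had a median width of 9.99 kb in replicate 1 and 9.06 kb in replicate 2, against 3.91 kb and 3.28 kb for the other shared regions.

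Among the regions at the ceiling, the highest series-wide score, 199.43, belonged to a peak on chromosome III from 11090744 to 11096933 in WS220 coordinates. It lay inside a replicate 1 peak of 23.8 kb and a replicate 2 peak of 20.9 kb. The second, with a score of 198.17, lay on chromosome V from 14021023 to 14028767, inside replicate peaks of 10.2 kb and 10.3 kb. On chromosome I the highest was the peak from 1845733 to 1853246, with a score of 197.11, for which the replicate 1 peak spanned 22.4 kb and the replicate 2 peak 8.44 kb, so that it was shared by 1 bp overlap and not by reciprocal overlap. On X there were 2 regions among the 20. One ran from 6243013 to 6255614 with a score of 189.36, and the other from 16564519 to 16573064 with a score of 187.04. On chromosome II the highest peak ran from 15013350 to 15026041 with a score of 189.14, near the right end of the chromosome. The only region of chromosome IV among the 20 ran from 9506986 to 9511911 with a score of 175.08.

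The remaining 13 regions of the 20 had series-wide scores down to 170.44. On chromosome I they were the peaks from 12166725 to 12174080, 4171966 to 4184502, 12284789 to 12295172, 2084773 to 2091403 and 12144654 to 12150437. Chromosome II held the peaks from 11535108 to 11539254, 6960380 to 6968661, 12938859 to 12945078 and 13521055 to 13531255. Chromosome III held those from 7134708 to 7140606 and 12249518 to 12253665, and chromosome V those from 9081103 to 9098347 and 14092337 to 14099510. The peak on V from 9081103 was the longest of the 20 in the series-wide list, at 17.2 kb, and its replicate peaks spanned 18.9 kb and 18.7 kb. The region on III around 7134708 held the widest replicate 1 peak of the genome, 37.7 kb, and 24.96 kb in replicate 2. Several of the chromosome I regions, which start at 12144654, 12166725 and 12284789, lay close together. In all, 6 of the 20 regions were on I, 5 on II, 3 on III, 1 on IV, 3 on V and 2 on X.

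Another comparison asked what the series-wide list held beyond the replicate lists. Of its 15152 peaks, 5857 (38.7%, interval 37.9 to 39.4%) overlapped a peak in both replicates, 3480 (22.97%) in replicate 1 only, 1850 (12.2%) in replicate 2 only and 3965 (26.2%, interval 25.5 to 26.9%) in neither. No shifted share was computed for these overlaps. The list also differs from the replicate lists in its named caller and its score floor, so its additional peaks need not be further sites. The peaks found in both were wider, with a median of 685 bp against 227 bp for those in neither, and held 68.6% of the covered bases, against 9.68%. Their median score was 9.72 against 4.81 for all other series-wide peaks, a difference of 4.91 (permutation test, two-sided, p = 1e-05, the smallest value 100000 resamples can give). The series-wide list can include reads of both replicates, so a higher score at peaks found in both may be built in. The test also treats peaks as independent, although several often lie in 1 replicate peak. Its p is therefore no separate evidence of agreement. In the lowest 10% of series-wide scores 20.2% of peaks were in both replicates and 40.3% in neither, and in the highest 10% 90.2% and 1.19%. In the other direction, 2827 replicate 1 peaks (99.6%) and 2813 replicate 2 peaks (98.9%) overlapped a series-wide peak. One replicate 1 peak held 3.3 series-wide peaks on average and at most 22, and one replicate 2 peak 2.74 on average and at most 16.

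A further comparison concerned the chromosomes. The 2037 replicate 1 peaks shared with replicate 2 were densest on chromosomes III and I, at 27.4 per Mb on each, and sparsest on X, at 12.5 per Mb. Chromosome II carried 22.2, IV 20.8 and V 15.4 per Mb. The autosomes averaged 22.7 ± 5.02 peaks per Mb (SD, n = 5 chromosomes), and pooled over their length the density of X was 0.569 of theirs. The 2188 shared peaks as listed in replicate 2 gave 31.5 per Mb on I, 29.7 on III and a ratio of 0.515 for X, where 218 of them lay. X was also the lowest chromosome in the replicate 1 list at 17.1 per Mb, in the replicate 2 list at 17.3 per Mb and in the series-wide list at 85.4 per Mb, against 171.08 ± 44.7 (SD, n = 5 autosomes). Shared peaks of replicate 1 covered 6.53% of X, 8.29% of V, 11.5% of IV, 12.7% of II, 15.7% of III and 16.8% of I. With 1 X and 5 autosomes the exact permutation p was 0.167, the smallest that 6 chromosomes allow, so the design cannot reach 0.05. V lay nearer to X than to I or III, and densities were not adjusted for the number of genes on each chromosome.

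**Figure D2:**
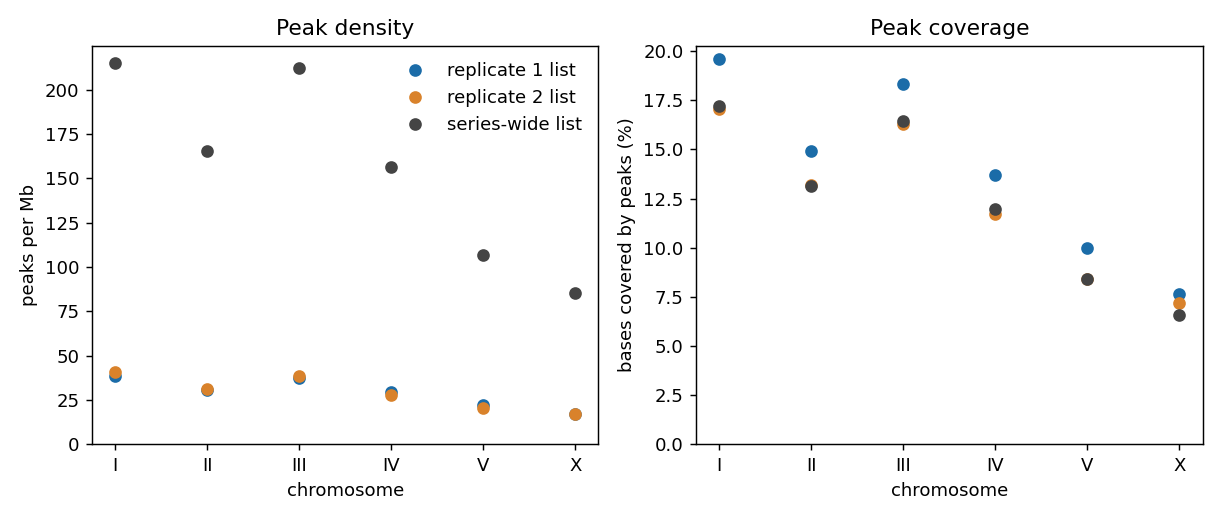
Peaks per Mb (left) and percent of bases covered by peaks (right) for each chromosome (x axis), one point per list (blue, replicate 1; orange, replicate 2; grey, series-wide). X is lowest in every list, at 17.1, 17.3 and 85.4 peaks per Mb, and V is next.

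Within chromosomes, AMA-1 peaks were denser towards both ends than in the middle. After the counts per Mb had been seen, each chromosome was divided into 3 parts of equal length, 1 middle and 2 outer, which are not the genetic boundaries of arms and centre. Shared peaks, again those of replicate 1, were 1.37 ± 0.0593 times as dense in the outer parts (mean ratio ± SD, n = 6 chromosomes, exact sign-flip permutation test, two-sided, p = 0.0312, the smallest possible). The ratio was above 1 on 6 of 6 chromosomes, from 1.32 on II to 1.48 on X. It was 1.49 in the replicate 1 list, 1.31 in the replicate 2 list, 1.37 in the series-wide list and 1.38 for the shared peaks of replicate 2. For peaks shared between the better-scoring 50% of each replicate list the mean ratio was 1.40, from 1.12 on IV to 2.06 on X, and compared with all shared peaks it was lower on I to IV and higher on V and X. In the highest 25% of scores the ratio over all chromosomes was 1.21 (interval 1.03 to 1.42) in the replicate 1 list and 1.07 (interval 0.911 to 1.25) in the replicate 2 list. Among shared peaks it was 1.11 (interval 0.921 to 1.34) for those of replicate 1 and 1.08 (interval 0.903 to 1.29) for those of replicate 2. Of the regions at the score ceiling, 62.5% (interval 55.0 to 69.5%) lay in the outer parts, which is 0.833 times the density of the middle part (interval 0.611 to 1.14, which includes equal density), against 73.7% of the other shared regions (Fisher's exact test, two-sided, p = 0.00268). That test was not planned and treats neighbouring regions as independent.

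Single stretches stood out at this scale. Over the 97 complete bins of 1 Mb, the series-wide list held a median of 143 peaks and ranged from 50 to 307. The fullest bins were 1 to 2 Mb on chromosome IV with 307 peaks, 12 to 13 Mb on III with 306 and 2 to 3 Mb on I with 304. The emptiest were 12 to 13 Mb on X with 50 peaks, and 3 to 4 Mb on V and 11 to 12 Mb on X with 54 each. The longest stretches without a peak in any list lay on V, from 364516 to 723346 (358.8 kb), from 3217190 to 3514539 (297.4 kb) and from 18132354 to 18427956 (295.6 kb). On X the longest such stretch ran from 11041906 to 11293347 (251.4 kb).

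**Figure D3:**
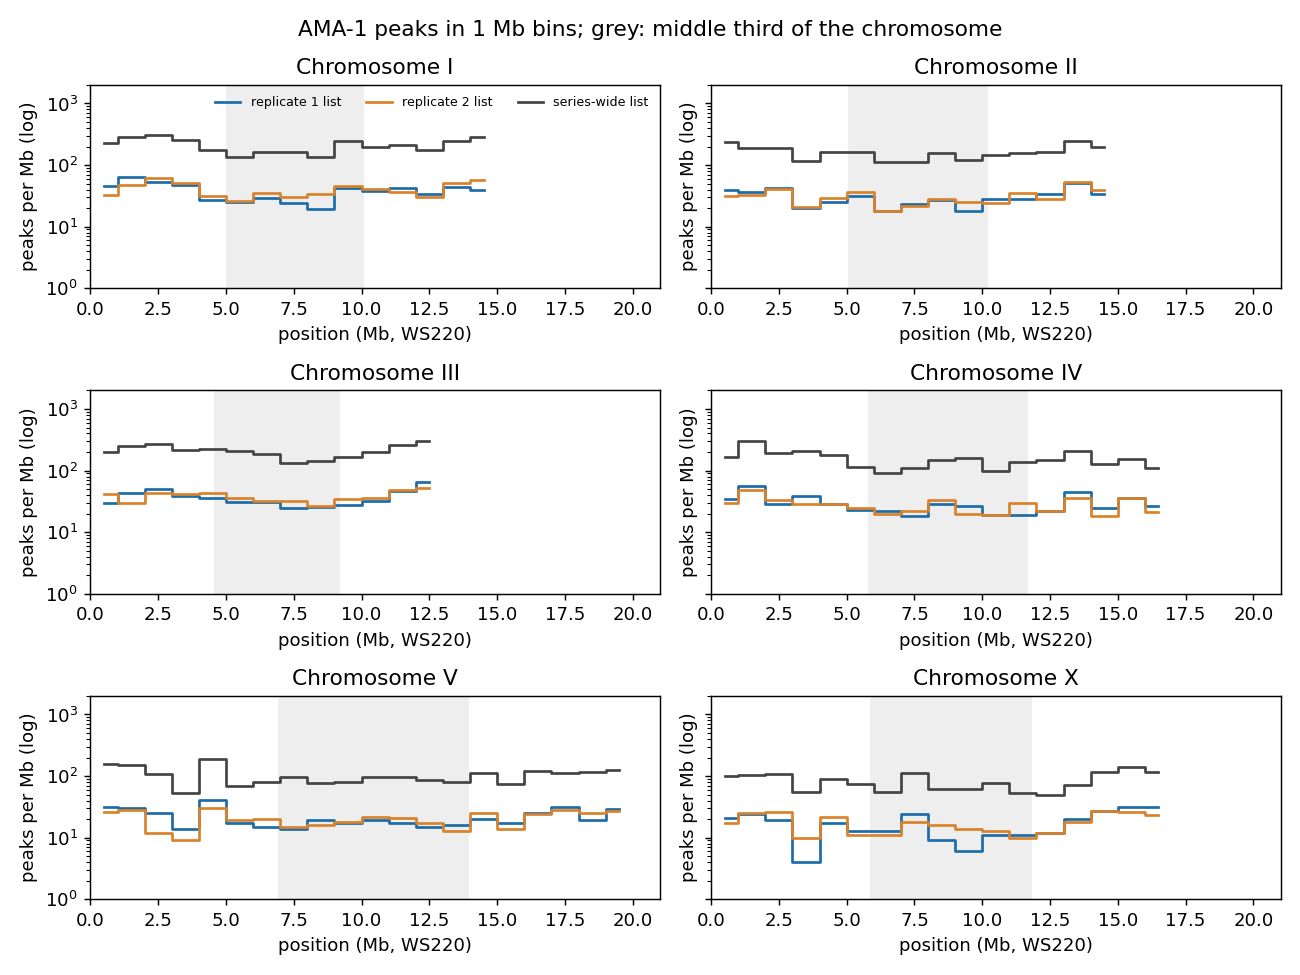
Peaks per complete 1 Mb bin (y axis, log scale) along each chromosome (x axis, Mb in WS220) for the series-wide list (grey line) and both replicate lists (blue, replicate 1; orange, replicate 2), with the middle part shaded. Outer bins hold more peaks than middle ones on average, and the bin at 3 to 4 Mb of V is among the emptiest, with 54 series-wide peaks.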

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

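The overlap between replicates stayed above the mean of its shifted lists, with p of 0.001 or 0.002, under all 10 alternatives in each direction, with shares from 56.2 to 73.3% of replicate 1 and from 56.1 to 78.8% of replicate 2 peaks. Single shifted lists reached more than the observed share on chromosome III for replicate 1 (73.31% against 73.11%) and on V for replicate 2 (79.7% against 78.8%). Circular shifts could have any length, including short ones that leave the lists nearly aligned, so these maxima need not be chance overlap. Local shifts of 50 to 200 kb, which keep regional density, gave 23.1% and 23.6% over all chromosomes, and at most 25.5% and 26.7%. The rank correlation of scores was 0.56 over every overlapping pair and 0.81 over reciprocal pairs, and that of widths was 0.50 and 0.93. The reciprocal rule keeps only pairs of similar width, so the higher correlation of widths there is at least partly built in. Why the correlation of scores moved was not tested. The share of series-wide peaks found in both replicates was 36.1% with 50% of the shorter peak required, 55.5% for the better-scoring 50% and 90.2% for the best-scoring 10% of the list. With 1 replicate list it ranged from 50.9% (without replicate 1) to 61.6% (without replicate 2), higher by construction, since only 1 list has to hold the peak. The score difference between series-wide peaks found and not found kept its direction under 5 of 5 alternatives, which reads common to the lists could also give. The density of X relative to the autosomes was 0.515 for shared peaks of replicate 2, 0.516 in the series-wide list and 0.654 for the better-scoring 50% (exact permutation p = 0.333 there), and 0.556 (without replicate 2) to 0.563 (without replicate 1) with 1 list. By covered bases it was 0.519, 0.507 in the series-wide list, 0.543 for shared peaks of replicate 2, 0.558 for the better-scoring 50%, and 0.515 to 0.556 with 1 list. The outer-to-middle ratio stayed above 1 under 10 of 10 alternatives, from 1.26 by covered bases to 1.53 for the best-scoring 10% of the series-wide list (1.23 on III to 2.13 on X). Those alternatives left out the highest 25% of replicate scores. There the ratio, pooled over all chromosomes and not averaged over them, was 1.21 and 1.07 in the whole lists of replicates 1 and 2. It was 1.11 and 1.08 among their shared peaks. For regions at the ceiling it was 0.833 (interval 0.611 to 1.14). Of the 20 named regions 19 stayed shared by reciprocal overlap and 19 by midpoint. No paired analysis was possible because the input libraries have no peak list of their own here. Gene windows, biotypes and gene features were not run for lack of an annotation in WS220 coordinates. Read depth is unknown, so a peak missing from a list was not shown to be absent.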

Other observations

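All tests in this part were chosen after the patterns they address had been seen. Scores were also compared between the outer and middle parts of each chromosome. In replicate 1 the median score on X was 365.9 in the outer parts and 240.8 in the middle part, and in replicate 2 it was 341.6 and 174.6. On V the outer median was also higher in both replicates, by less, and on I, II, III and IV it was lower in both. The largest opposite difference was on II, with 282.5 and 536.6 in replicate 1 and 217.7 and 408.4 in replicate 2. A chance arrangement along the chromosome could give differences of this size. Rotating the scores along X gave p = 0.191 in replicate 1 and p = 0.0293 in replicate 2 (permutation tests, two-sided, 12 in the family), and the larger adjusted p was 0.328, so the difference on X did not pass. On II the rotation p was 0.0557 and 0.0823 (adjusted p 0.222 in each), which did not pass either.

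Peaks near chromosome ends were present in every list. At the left end of chromosome I, replicate 1 had a peak from 2 to 4814 with a score of 2042.48, replicate 2 one from 2 to 5054 with a score of 2453.4, and the series-wide list one from 542 to 4585 with a score of 124.89. The last peak of chromosome III, from 13766870 to 13771505 in replicate 1 and from 13767329 to 13772479 in replicate 2, had scores of 1287.2 and 1078.5. In the series-wide list the last one there ran from 13771996 to 13772216, with a score of 4.5. It began past the end of the replicate 1 peak and lay inside the replicate 2 peak, and scores are not comparable between lists. At the left end of X, peaks began at 1 in replicate 2 (to 882, score 82.68) and at 7830 in the series-wide list (score 19.02). The first replicate 1 peak of X began at 42816 and had a score of 1724.1. On V the series-wide list began with a peak from 3407 (score 2.08).

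The higher density of peaks in the outer parts was examined against technical explanations. Merging of neighbouring sites into wide peaks in the middle would by itself leave covered bases equal, but covered bases per Mb were higher in the outer parts on 6 of 6 chromosomes in the series-wide list and for the shared peaks of replicate 1. In the replicate lists a part for merging stays open, since median widths on the autosomes were 3632 bp in the middle and 2853.5 bp in the outer parts for replicate 1, and 3009 bp and 2605 bp for replicate 2. On X they were 3524.5 bp in the middle and 3191 bp in the outer parts for replicate 1. For replicate 2 the order on X was reversed, at 2976 bp and 3085.5 bp. Weak calls near the score floor are argued against for the series-wide list, in whose best-scoring 10% the mean ratio was 1.53 ± 0.134 (SE over 6 chromosomes). Pooled over all chromosomes, as are the replicate ratios by score below, it was 1.46 (interval 1.30 to 1.64). One library or one caller alone would leave a list without the pattern, but each of the 3 lists had a ratio above 1 on 6 of 6 chromosomes. This prediction was written after the data had been seen, so the count describes the pattern in each list and is no separate test. The series-wide list can also include reads of both replicates. In the replicate lists the part of weaker calls stays open, since among the shared peaks of replicate 1 the ratio was 1.11 (interval 0.921 to 1.34) in the highest 25% of scores and 1.47 (interval 1.21 to 1.8) in the next 25%. In the whole lists the highest 25% had a ratio of 1.21 (interval 1.03 to 1.42) in replicate 1 and 1.07 (interval 0.911 to 1.25) in replicate 2. Gene density, mappability and input coverage were not tested and stay open too.

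Replicate 1 peaks missing from the replicate 2 list numbered 801. A small displacement, leaving a gap of at most 1000 bp, is argued against for most of them. Only 16.6% of them (interval 14.2 to 19.3%) had a replicate 2 peak within 1000 bp, and their median distance to one was 5.23 kb. No chance share within that distance was computed, and larger displacements were not tested. Weak calls under the score floor of the other list and lower signal outside replicate 1 stay open. The steeper recovery of high scores, 64.7 percentage points more of the peaks not matched by chance in the highest than in the lowest 25%, restates the pattern. The series-wide score at missing peaks, different by −0.70 on the log2 scale (missing minus shared) at similar replicate 1 score, does not decide either, because that list can include replicate 2 reads.

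A few peaks at the score ceiling had no partner. In replicate 1, 4 of 286 peaks at or above the score ceiling overlapped no replicate 2 peak. They lay on I from 3989535 to 3999561, III from 12542834 to 12561992, IV from 14778816 to 14794843 and V from 15355921 to 15361497. In replicate 2, 2 of 195 did so, on II from 14396935 to 14408821 and on IV from 11606408 to 11619657. Each of the 6 overlapped at least 2 series-wide peaks, with highest scores from 31.65 to 102.59, and the nearest peak of the other list was between 360 bp and 24121 bp away.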
